A study of Caenorhabditis elegans with 2 samples.

How the data were processed

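The series was made to locate a tagged transcription factor on the genome of Caenorhabditis elegans. Whole L4 larvae (the last larval stage) of a hermaphrodite strain carried an integrated transgene that expresses DUXL-1, a homeodomain protein, with a GFP and FLAG tag at its C-terminal end, per the labels. Chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. Both samples are biological replicates of the same group, so no groups were compared and every result describes these 2 libraries. A control library was used by the authors when peaks were called, per the deposited README files, and is not analysed here.

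The deposited files are lists of peaks in builds ce10 and ce11. For each build there is a candidate list per replicate, a candidate list called on the pooled replicates and a list thresholded on the irreproducible discovery rate (IDR), per the deposited README files. The candidate lists include background regions on purpose, as input for the IDR step, and hold 30000 regions each. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each region has a signal value, the enrichment the authors' peak caller assigned to it, and a -log10 q value, as deposited by the authors. Each region also has the distance of its summit from its start, likewise given in the deposited files. The -log10 q has a ceiling of 2.43 that all 1980 thresholded ce11 peaks share, so only the signal was used to order peaks. Signal is not scaled between lists and was used to describe and rank peaks within a list. The thresholded ce11 list was checked against the pooled candidates and equals the 1980 candidates with the highest signal, with the cut falling at a signal of 65.0, so a peak in it need not rank alike in both replicates. The number of reads behind each library is unknown, since the lists hold no counts, so intervals given for shares are 95% Wilson intervals over peaks or genes and cover counting error only.

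Analyses used the ce11 list with the WBcel235 genome sequence and the Ensembl annotation of that build. No region extended beyond the end of a chromosome of that sequence, and no coordinates were converted. Mitochondrial peaks were left out of tests on chromosomes, features, genes and words, which leaves 1965 nuclear peaks. A thresholded peak counted as found in a replicate when it overlapped, by at least 1 bp, one of the 1980 candidates of that replicate with the highest signal. The overlap of the replicates' top candidates was set against 1000 circular shifts of one list along each chromosome in a one-sided permutation test. Peaks per chromosome were tested against chromosome length with two-sided exact binomial tests. Summits were assigned, in order, to promoters (1000 bp upstream to 200 bp downstream of a start of a protein-coding transcript), 5 prime UTR, coding exon, 3 prime UTR, intron, non-coding RNA gene, or intergenic sequence with pseudogenes, and compared with 10000 circular shifts in two-sided permutation tests. Shares of 18 gene lists with a promoter peak were compared with all other protein-coding genes by two-sided Fisher's exact tests. A small constant was added to each count for the odds ratios. As an alternative, the share of each list among all genes with a promoter peak was compared with circular shifts. The lists were homeobox genes, nuclear hormone receptors, cuticle collagens, hedgehog-related and molting genes, ribosomal proteins, histones, vitellogenins and intestine, body wall muscle, pharynx, pan-neuronal genes, neuropeptides, cilia, germline, sperm, heat shock, Wnt, Notch and EGF signalling, proteasome and vacuolar ATPase, all by gene symbol. A set of 13 sequence words was searched on both strands within 50 bp of the summit and in windows of the same length centred 300 bp to the left and right, with two-sided exact McNemar tests, keeping the larger p of both flanks. All 2080 strand-collapsed words of 6 bases were then compared by Fisher's exact tests. The surroundings of duxl-1 and unc-119 (the gene named as mutant in the strain) were compared with 10000 random windows of the same length, one-sided. Families of tests were adjusted by Benjamini-Hochberg at a threshold of 0.05. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

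The tests, lists, words and alternatives above were fixed before the data were examined, as was the rule for named genes. That rule takes the nearest protein-coding start within 1000 bp of each of the 25 thresholded peaks with the highest signal that are found among the top candidates of both replicates (both genes of a divergent pair), duxl-1 and unc-119 in any case, and up to 4 members of each gene list by the signal of their promoter peak. Peaks without such a start are given by position. Because 12 of these 25 peaks are mitochondrial, the rule was also applied to nuclear peaks alone, a choice made after the values were seen. The tests of non-coding gene classes (a summit within 100 bp of the gene, 10000 circular shifts), of the 100 strongest nuclear peaks and of their clustering were also chosen after the data were seen. Alternatives covered a stricter peak list, each replicate's own list in place of the thresholded one, other overlap rules, promoter windows, backgrounds and word windows, and the ce10 list.

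The tests were checked on simulated summits. Of 100 sets of 2000 random summits, 5% fell below 0.05 in the promoter test, 2% in the test of chromosome X and 3% in the test of tRNA genes. With a planted effect, the test found it in 20 of 20 simulated sets for the promoter share, chromosome X, the gene lists, the sequence words and the tRNA genes alike. The mean estimate was 7.22 percentage points for the promoter share against a planted 7.38, and 31.7% of tRNA genes against a planted 30%. Simulated summits and gene hits were drawn independently of each other, whereas some of the real peaks cluster and some genes share a peak. These checks therefore do not show that the binomial and Fisher's exact tests keep their error rate on the real peaks.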

Results

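Anti-GFP chromatin immunoprecipitation was followed by sequencing in 2 biological replicates of whole L4 larvae that express tagged DUXL-1 from a transgene. The labels describe 1 tagged protein at 1 stage, so the question addressed is where on the genome peaks of this precipitation lay, and in which kinds of genes. No control precipitation is analysed here, so a peak need not mark binding by DUXL-1. The thresholded list held 1980 peaks in ce11, of which 1965 were nuclear and 15 mitochondrial. Peaks had a median width of 280 bp and a median signal of 94.6, in the units the authors' peak caller assigned, with a range from 65.0 to 3383. The ce10 list held 1927 peaks, 53 fewer. Signals at the same rank of the thresholded lists differed by at most 0.489% between builds, and by up to 10.9% for the candidates of replicate 1. Only 1299 of the 1927 ranks compared held a peak on the same chromosome in both builds. Peaks were not matched by position, so whether both lists hold the same peaks was not tested. Depth in reads is unknown.

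Most thresholded peaks had a candidate in both replicates, and the stronger ones were also among the top candidates of both. Of the 1980 thresholded peaks, 96.0% overlapped some candidate of both replicates. Of the 1980 thresholded peaks, 1450 (73.2%) overlapped a top candidate of replicate 1 and 1375 (69.4%) one of replicate 2. Top candidates of both replicates were overlapped by 1033 peaks, or 52.2% (95% Wilson interval 49.97 to 54.4), and top candidates of neither by 188. This share was 85.2% among the 990 peaks with the higher signal and 19.2% among the 990 with the lower signal. The weaker peaks lie closer to the limit of the top lists, but some fell far below it in a replicate. Examples are the peaks at dnj-22 (rank 16844 in replicate 1) and spe-36 (rank 12861 in replicate 2). How much of the lower share the limit accounts for was not tested. Of the 100 strongest nuclear peaks, 99 were found among the top candidates of both replicates. The top candidates of replicate 1 overlapped those of replicate 2 in 53.9% of cases (interval 51.7 to 56.1). On nuclear chromosomes the overlap was 53.6%, against a mean of 1.01% after circular shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Across 1886 nuclear peaks with a candidate in both replicates, the Spearman correlation of signal was 0.463, which is across peaks, and peaks are not independent replicates. Requiring a reciprocal overlap of 50% lowered the share found in both replicates to 36.5%.

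The strongest peaks lay on mitochondrial DNA and on chromosome X, followed by promoters of ribosomal protein genes. Among the 25 strongest peaks found in both replicates, 12 were mitochondrial, 12 lay on X and 1 lay on an autosome. The mitochondrial peaks had signals between 1451 and 3383, and their nearest protein-coding starts were those of ND1 (a subunit of NADH dehydrogenase), COX3 (a subunit of cytochrome c oxidase) and genes listed by identifier only, WBGene00010960, WBGene00010961, WBGene00010964, WBGene00010965 and WBGene00000829. These starts give positions only, and whether tagged DUXL-1 binds mitochondrial DNA was not tested. The autosomal peak, at chromosome V 18723630 to 18723982, had a signal of 1923 (962 and 971 in replicates 1 and 2), with no protein-coding start within 1000 bp and no annotated gene at its summit. On X, the peak at 1344782 to 1345291 had a signal of 1119 (584 and 548 in the replicates) and its summit lay 638 bp upstream of ins-39, which encodes an insulin-like peptide. The peak at 1989634 to 1989960 had a signal of 1116 (604 and 516) between the divergent genes meg-3, which encodes a germ granule protein, and Y40A1A.2. The other X peaks with a start within 1000 bp lay upstream of fbxb-58 (signal 1051) and nspc-17 (signal 991). Those without one had summits at X 11094204, 9465852, 4209273, 6296566 (inside the gene mom-1), 2997107 (inside Y41G9A.17), 11937554, 13700877 and 16682107, with signals from 1112 down to 885.

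With the rule applied to nuclear peaks alone, 17 of the 25 peaks lay on X and 8 on autosomes, and 14 had no protein-coding start within 1000 bp. Of the 8 autosomal ones, 6 had such a start. The strongest of these was 280 bp upstream of rpl-3 on chromosome III (3867464 to 3867688, signal 853, with 446 and 407 in the replicates). Further ones lay upstream of rpl-35 (signal 791), between rpl-20 and Y17G9B.5 (787), upstream of tasp-1 and K01G5.10 (729), between rpl-15 and K11H12.8 (678) and upstream of cdc-48.1 (638), which encodes an AAA ATPase. rpl-3, rpl-35, rpl-20 and rpl-15 encode proteins of the large ribosomal subunit. A peak at chromosome V 8500424 to 8500656 (signal 639) lay inside pxn-1, next to the snoRNA gene ZK994.7. On X, meg-4, a paralog of meg-3, had a peak 188 bp upstream of its start (signal 780). The other added X peaks had no such start, with summits at X 806686 (signal 880), 5429538 (863, inside pks-1), 8036405 (840) and 1909567 (812).

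**Figure D1:**
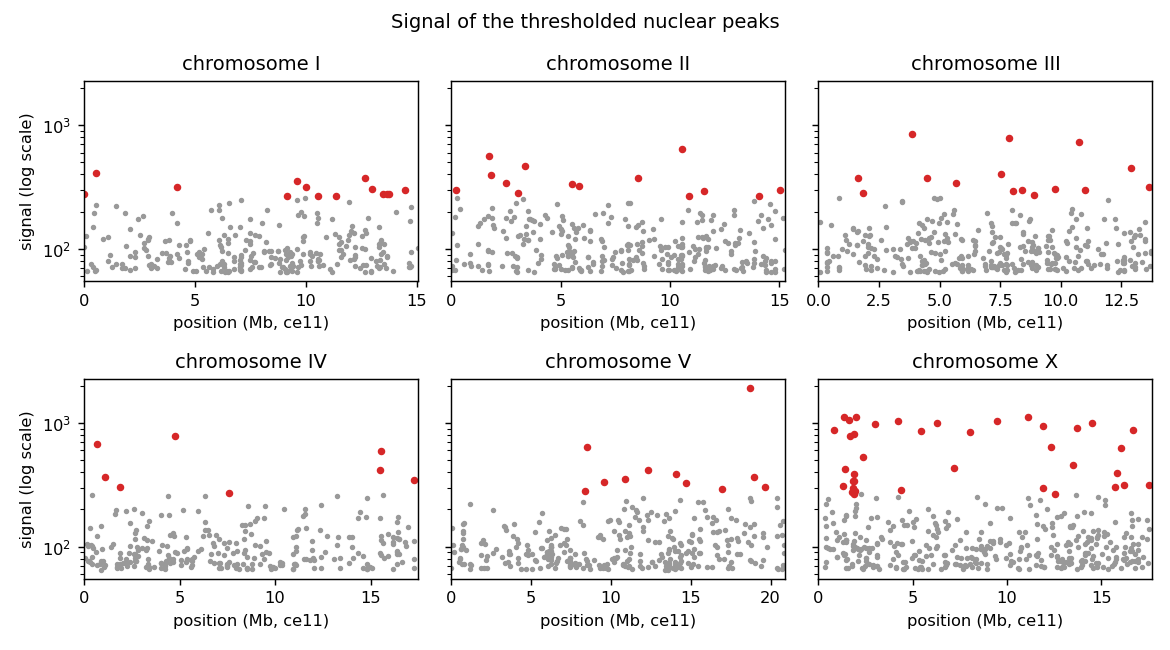
Signal of the thresholded nuclear peaks (log scale) against position in Mb along each chromosome of ce11, with the 100 strongest nuclear peaks in red and all others in grey. Of the red points, 38 lie on X, where they reach signals of 1119, and the single highest point lies on chromosome V at 1923.

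Peaks were unevenly spread over the chromosomes, and the strongest were concentrated on X. Chromosome III held 344 of 1965 nuclear peaks (17.5%, interval 15.9 to 19.2), 1.27 times the number given by its length (adjusted p = 8.2e-06, exact binomial test). Chromosome X held 405 peaks (20.6%, 18.9 to 22.5), 1.17 times its share of the length (adjusted p = 0.00124, exact binomial test). Chromosomes IV and V held fewer, at 0.823 and 0.795 times (adjusted p = 0.000506 and 8.2e-06, exact binomial tests), and chromosomes I and II were at 0.955 and 1.09 times without passing the test (adjusted p = 0.412 and 0.115, exact binomial tests). Of the 100 strongest nuclear peaks, 38 lay on X, 2.15 times the length expectation (p = 2.1e-06, exact binomial test), against 367 of the other 1865 (Fisher's exact test, p = 3.7e-05). The share on X among the 100 strongest candidates was 34% in replicate 1 and 39% in replicate 2. With each chromosome cut into 3 equal parts, 38.3% of autosomal peaks fell in the central part (adjusted p = 0.000308, exact binomial test), and 27.7% of X peaks did (adjusted p = 0.0267, exact binomial test), against 33.3% by length, although X did not pass with either replicate's own list (28.4% and 28.9%) or in the stronger 990 peaks (26.1%). The autosomal excess came from chromosomes I (44.0%), III (40.1%) and V (39.0%), while II (34.7%) and IV (33.7%) did not pass (adjusted p = 0.745 and 0.9, exact binomial tests). In the stronger 990 peaks no single chromosome passed. The excess on X over all peaks depended on peaks at small RNA genes: without the 371 peaks within 100 bp of a tRNA, snoRNA or snRNA gene the ratio was 0.948 (adjusted p = 0.429, exact binomial test). Without these peaks chromosome II passed at 1.13, as it did at 1.16 in the stronger 990 peaks (adjusted p = 0.0421 and 0.0388, exact binomial tests). It was at 0.979 with all pooled candidates as background. With all pooled candidates as background, chromosomes III, IV and V were at 1.04, 0.971 and 0.917 times and no longer passed, and among the stronger 990 peaks the autosomal central share was 36.3% (p = 0.0881, exact binomial test).

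Summits were gathered at promoters and were rare in coding exons. Of 1965 nuclear summits, 1071 (54.5%, interval 52.3 to 56.7) lay from 1000 bp upstream to 200 bp downstream of a protein-coding start, against 25.9% of shifted summits (permutation p = 1e-04, the smallest that 10000 shifts can give). The median distance to the nearest protein-coding start was 544 bp, against 1321 bp for shifted summits. Coding exons held 6.36% of summits against 18.8% shifted, introns 15.2% against 27.5%, and intergenic sequence with pseudogenes 17.8% against 24.2% (adjusted permutation p = 1e-04 for each). With lower-ranked candidates as background, the ratio for intergenic sequence turned to 1.11 without passing (adjusted p = 0.0551, Fisher's exact test). The 3 prime UTRs held 1.42% against 2.39% (adjusted permutation p = 0.0065), a difference that did not pass with either replicate's own list. The 5 prime UTRs held 0.254% against 0.417% (adjusted permutation p = 0.305). Features differed between X and the autosomes: 38.3% of X peaks lay at promoters, against 58.7% of autosomal ones (Fisher's exact test, adjusted p = 8.1e-13). Shifted summits were not counted for X and autosomes apart, so a difference in promoter coverage is not accounted for. Peaks at small RNA genes were included, which made up 34.1% of X peaks and 14.9% of autosomal peaks. Of the 100 strongest nuclear peaks, 7 of 38 on X and 49 of 62 on autosomes lay at promoters (Fisher's exact test, p = 2.4e-09).

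Genes for tRNA and other small RNAs carried peaks far more often than shifted summits gave. Summits in non-coding RNA genes made up 4.43% of all nuclear summits, against 0.786% shifted (adjusted permutation p = 1e-04). Within 100 bp of the gene, 279 of 612 tRNA genes (45.6%, interval 41.7 to 49.5) had a summit, against 0.566% with shifted summits. The same held for 80 of 346 snoRNA genes (23.1%, 18.99 to 27.8), which encode guides for RNA modification, and for 22 of 129 snRNA genes (17.1%, 11.5 to 24.5), which encode spliceosomal RNAs, against 0.662% and 0.581% (permutation p = 1e-04 for each, the smallest that 10000 shifts can give, and 0.0002 after adjustment over 8 classes). Peaks were also found at 3.45% of 261 miRNA genes and 7.22% of 194 lincRNA genes, against 0.59% and 2.71% (adjusted permutation p = 0.0003 and 0.0015), neither of which passed in the stronger 990 peaks, whereas pseudogenes were at 0.94% against 2.91% (adjusted permutation p = 0.0002). The large class annotated only as ncRNA was at 4.82% of 7764 genes against 0.715% (adjusted permutation p = 0.0002), and none of 20 nuclear rRNA genes had a peak (adjusted permutation p = 1). On X, 137 of 276 tRNA genes had a peak (49.6%) and on autosomes 142 of 336 (42.3%), a difference that did not pass (Fisher's exact test, p = 0.0731) but did with replicate 2 alone and in the stronger 990 peaks (Fisher's exact test, p = 0.0327 and 0.0258). Chromosome X holds 45.1% of the tRNA genes, and peaks at tRNA, snoRNA or snRNA genes made up 34.1% of X peaks and 14.9% of autosomal peaks (Fisher's exact test, p = 1.2e-16). Peaks at tRNA genes had a median signal of 105 and peaks at snoRNA genes 154. They made up 13.5% and 4.12% of all nuclear peaks, and 4 and 6 of the 100 strongest. When the summit had to lie inside the gene, 21.2% of tRNA genes and 5.2% of snoRNA genes had a peak.

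**Figure D2:**
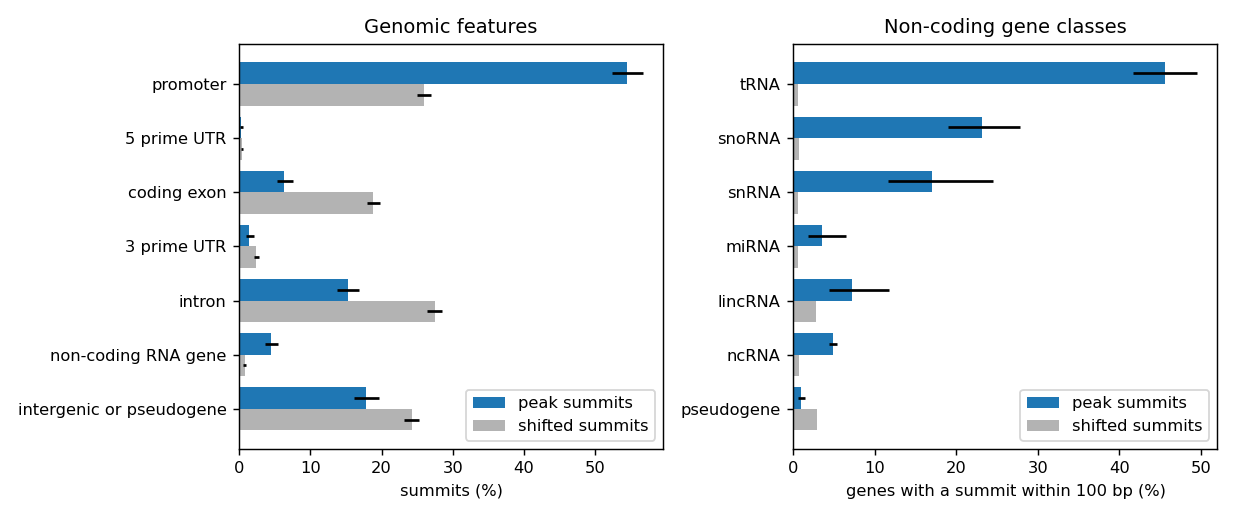
Left, percent of nuclear summits in each feature (blue, with 95% Wilson intervals) and mean percent of shifted summits (grey, with SD over 10000 shifts). Right, percent of genes of each non-coding class with a summit within 100 bp (blue, with 95% Wilson intervals) and the mean for shifted summits (grey), where tRNA genes reach 45.6% against 0.566%.

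Of the 6 lists that passed, promoter peaks were more frequent than at other genes for ribosomal proteins, the proteasome, chaperones and histones, and less frequent for neuropeptides and collagens. Of 19973 protein-coding genes, 1343 (6.72%) had a promoter peak. Of 81 ribosomal protein genes, 41 had one (50.6%, odds ratio 14.6, interval 9.45 to 22.6, Fisher's exact test, adjusted p = 1.3e-25), led by rpl-3, rpl-35, rpl-20 and rpl-15. Of 33 proteasome genes, 9 had one (odds ratio 5.41, 2.55 to 11.5, Fisher's exact test, adjusted p = 0.00145), led by rpn-11 (signal 158), rpn-3 (138), rpt-6 (111) and pas-4 (96.4). Of 52 heat shock genes, 13 had one (odds ratio 4.78, 2.57 to 8.88, Fisher's exact test, adjusted p = 0.000262), led by the chaperone genes hsp-60 (signal 377), hsp-90 (326), dnj-13 (291) and dnj-9 (229). Of 72 histone genes, 13 had one (odds ratio 3.17, 1.75 to 5.73, Fisher's exact test, adjusted p = 0.00417), led by his-37 (signal 334), the pair his-67 and his-68 with a shared peak (315) and his-3 (172). These 13 histone genes rest on 8 distinct peaks, and the 41 ribosomal protein genes on 38. Some peaks were also counted in different lists: rpn-3 shares its peak with the heat shock gene hsp-110, the collagen gene col-38 with rpl-5, and the nuclear hormone receptor gene nhr-47 with dnj-19. Fisher's test counts such genes as independent, whereas circular shifts keep shared peaks together. Cuticle collagen genes had peaks at 3 of 176 (col-185, col-71 and col-38, odds ratio 0.278, 0.0963 to 0.801, Fisher's exact test, adjusted p = 0.0132). Neuropeptide genes had peaks at 2 of 142 (ins-39 and ins-13, odds ratio 0.245, 0.0701 to 0.858, Fisher's exact test, adjusted p = 0.0188). Of the peaks named here, those at ins-13 and pas-4 were among the top candidates of replicate 1 only. The comparison with circular shifts tested the share of each list among all genes with a promoter peak, so a general preference for promoters was not counted. In it, only the ribosomal protein list passed (adjusted permutation p = 0.0018), while proteasome and heat shock were each at 0.0558, histones at 0.129, collagens at 0.518 and neuropeptides at 0.382 (adjusted permutation p). The ratios of these lists' shares to the shifted shares were 4.32, 3.404, 3.44, 0.293 and 0.223, in the same direction as the odds ratios. The proteasome and neuropeptide lists also did not pass with replicate 1 alone (odds ratios 3.53 and 0.482, adjusted p = 0.0564 and 0.229, Fisher's exact test). Nor did the collagens with replicate 2 alone (odds ratio 0.498, adjusted p = 0.237, Fisher's exact test).

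The other 12 lists did not pass the test in the main setting. Without peaks at small RNA genes, the vitellogenin and intestine list passed, as did the hedgehog-related and molting list (odds ratios 0.0811 and 0.0769, Fisher's exact test, adjusted p = 0.0118 for each). The vitellogenin and intestine list also passed from 500 bp upstream to 100 bp downstream (0.0988, Fisher's exact test, adjusted p = 0.0393). The promoter peaks of these lists, at cpr-9, wrt-3 and grl-26, all lay within 100 bp of a tRNA, snoRNA or snRNA gene. In each of these settings no gene of the list kept a peak, so the odds ratios rest on the constant added to each count. Homeobox genes had promoter peaks at 7 of 106, or 6.6%, close to the 6.72% of all genes. The strongest of these were ceh-83 (signal 569), ceh-38 (195), duxl-1 itself (184) and the Hox gene lin-39 (102). Nuclear hormone receptor genes had peaks at 15 of 274, led by nhr-68 (signal 197), nhr-255 (159), nhr-47 (158) and nhr-156 (154). Germline genes had peaks at 5 of 72, led by meg-3 (1116), meg-4 (780), puf-9 (133) and cgh-1 (126). The pharynx list had peaks at 7 of 95 genes, led by pqn-71 (228), pqn-59 (151), pqn-70 (98.4) and pqn-51 (87.4). These entered the list by the prefix of their symbol, and their expression in the pharynx was not checked. Sperm genes had peaks at 4 of 88, which were spe-9 (113), spe-39 (103), spe-5 (91.6) and spe-36 (79.0). The vitellogenin and intestine list had a peak at 1 of 93 genes, cpr-9 (246), the hedgehog-related and molting list at 2 of 98, wrt-3 (214) and grl-26 (142), and body wall muscle at 1 of 44, act-2 (68.2). Cilia genes had peaks at 2 of 61, ift-43 (79.1) and daf-19 (67.2), Wnt, Notch and EGF signalling genes at 1 of 34, wrm-1 (160), and vacuolar ATPase genes at 2 of 20, vha-15 (96.3) and vha-13 (74.1). The peaks at act-2, daf-19 and vha-13 were not among the top candidates of either replicate. Those at spe-9, spe-5, spe-36 and vha-15 were among the top candidates of 1 replicate only. Pan-neuronal genes had a peak at 0 of 25, which allows a share of up to 12%.

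**Figure D3:**
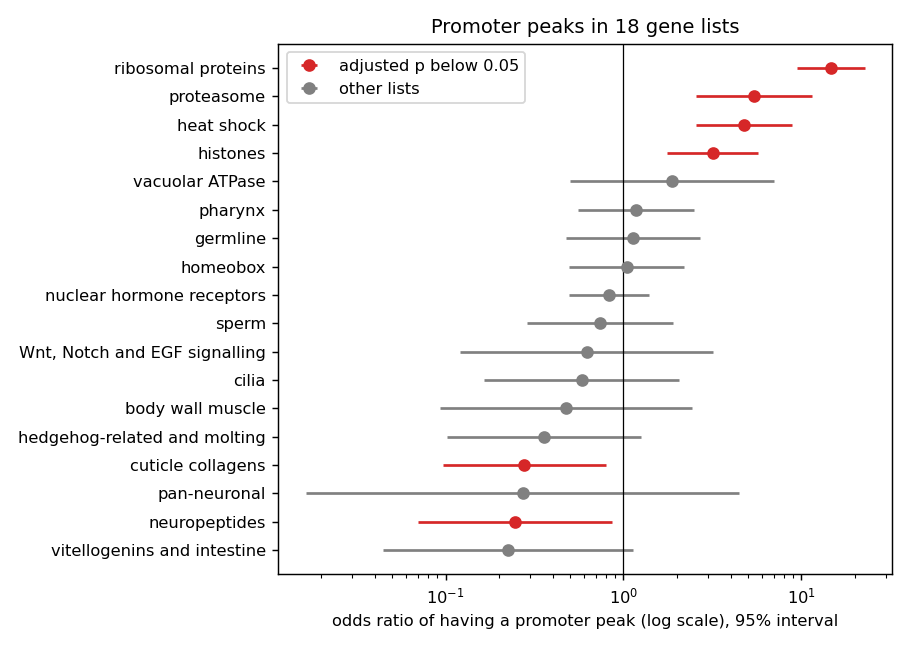
Odds ratio of having a promoter peak (log scale) for each of 18 gene lists against all other protein-coding genes, with 95% intervals, in red where the adjusted p of Fisher's exact test was below 0.05. Ribosomal proteins stand highest at 14.6, and neuropeptides and cuticle collagens are the lists below 1 that passed.

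Sequences at the summits were rich in G and C and poor in the homeodomain core TAAT. Windows within 50 bp of the summit had a GC content of 46.5%, against 35.4% and 35.5% in the left and right flank windows. TAAT was present in 41.0% of 1965 windows and in 65.5% of flank windows (ratio 0.626, exact McNemar test, adjusted p = 8.5e-51). The longer homeodomain words TAATTA (1.58% against 5.75%), TAATCA (3.46% against 6.46%) and TAATCC (1.83% against 3.38%) were also less frequent at summits (exact McNemar tests, adjusted p = 5.1e-12, 4.0e-05 and 0.00493). The site of human DUX4, TAAYYYAATCA, was present in 0 of 1965 windows, which allows a share of up to 0.153%, and in 0.153% of flank windows, so no difference was detectable. The paired words TAATNNATTA, TAATNNNATTA and TAATYNAATTA were present in 6, 3 and 2 windows and did not pass (exact McNemar tests, adjusted p = 0.15, 0.0829 and 1).

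GAGAGA was present in 21.1% of summit windows against 5.8% of flanks (ratio 3.64, exact McNemar test, adjusted p = 4.7e-43), and the E-box CACGTG in 4.33% against 1.73% (ratio 2.5, exact McNemar test, adjusted p = 7.0e-06). TTTAAA was lower, at 5.8% against 18.1% (exact McNemar test, adjusted p = 2.9e-30), as was the GATA word TGATAA, at 7.23% against 9.9% (exact McNemar test, adjusted p = 0.0067), and TGACGTCA did not pass (0.712% against 0.382%, exact McNemar test, adjusted p = 0.31). Of all 2080 words of 6 bases, 764 were more frequent and 458 less frequent at summits by Fisher's exact test with adjustment. Of the words that were more frequent, 739 held 3 or more G or C bases. The leading ones were ACGCAG (14.4% against 2.06%), GACGCA (13.6% against 2.01%), GAGAGA, AGAGAG (18.1% against 4.22%) and AGACGC (13.4% against 2.21%). Against shuffled copies of the same windows that keep their dinucleotides, TAAT was at a ratio of 0.921, GAGAGA at 2.18 and CACGTG at 1.93, and all 3 still passed. In that comparison TAATTA and TAATCA no longer passed (0.752 and 0.762), TTTAAA was at 1, TAATCC still passed (0.583, Fisher's exact test, adjusted p = 0.00313), TGACGTCA newly passed (5, Fisher's exact test, adjusted p = 0.000154), and TGATAA turned to a higher share (1.54, Fisher's exact test, adjusted p = 3.6e-05). Against the flanks, TAATCC did not pass with replicate 2 alone (0.718) or within 25 bp of the summit (0.615), nor did TGATAA with replicate 1 alone (0.817) or within 25 bp (0.772) (exact McNemar tests, adjusted p = 0.159, 0.329, 0.148 and 0.349).

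**Figure D4:**
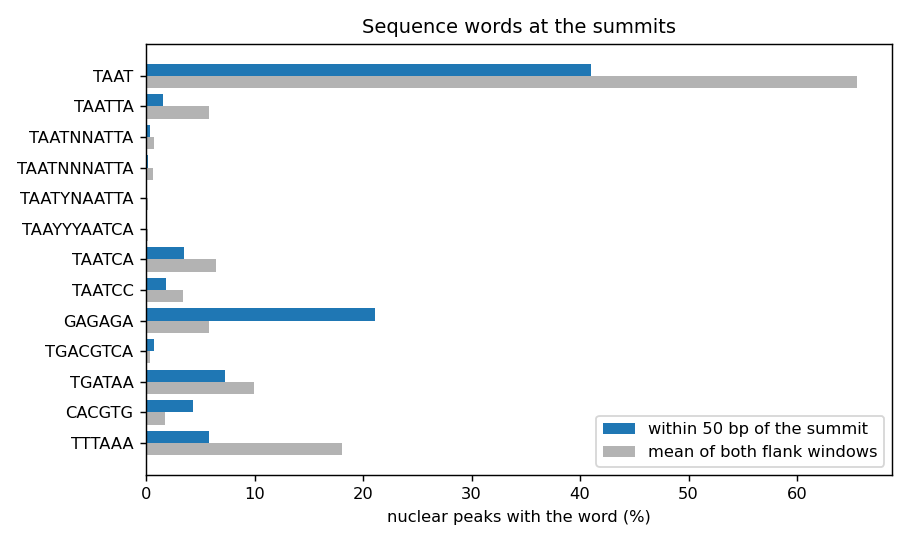
Percent of 1965 nuclear peaks that contain each word on either strand within 50 bp of the summit (blue) and mean percent in both flank windows (grey). TAAT falls from 65.5% in the flanks to 41.0% at the summit, and GAGAGA is at 21.1% against 5.8%.

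Candidates were dense around duxl-1. Within 20 kb of duxl-1 (chromosome II, 1663699 to 1665766, plus strand) there were 38 pooled candidates, against a mean of 12.5 in random windows of the same length (one-sided permutation p = 0.0032), with 34 in each replicate's own list. Of these, 5 were thresholded peaks, against a mean of 0.827 (one-sided permutation p = 0.0147). The strongest had its summit 34 bp downstream of the annotated duxl-1 start, with a signal of 184 and rank 245, and ranked 129 in replicate 1 and 352 in replicate 2. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935, plus strand) there were 3 pooled candidates, against a mean of 13.9 (one-sided permutation p = 0.92), and 0 thresholded peaks. Whether the transgene carries unc-119 sequence of this species is not in the labels, so the count at unc-119 does not bear on the transgene. The strain carries duxl-1 sequence in its transgene as well as at the native locus, and the peak lists do not tell the copies apart.

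**Figure D5:**
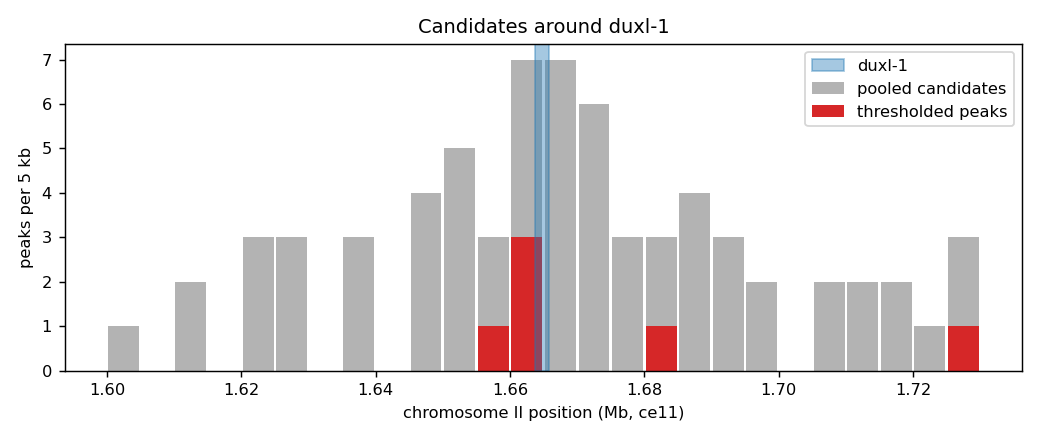
Number of pooled candidates (grey) and of thresholded peaks (red) in windows of 5 kb along chromosome II of ce11, with the duxl-1 gene in blue. Candidates reach 7 per window at duxl-1, and 38 lie within 20 kb of the gene.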

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

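The tests on weak X candidates, on the word near X peaks, on tRNA genes with several copies and on the density around duxl-1 were chosen after the results they measure had been seen, and the others after the pattern but before their own result. The series holds 1 group, so no biological explanation was tested against another condition.

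Signal outside the nuclear chromosomes, which the comparisons did not use, came from 15 thresholded peaks on the 13794 bp mitochondrial chromosome. They took 12 of the 13 highest ranks and had a median signal of 2203, against 94.2 for nuclear peaks. Whether this signal reflects binding by tagged DUXL-1 cannot be told from the peak lists, since the control library is not analysed here.

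The first pattern is the excess of X among the strongest nuclear peaks, 38 of 100. More X-linked DNA in the libraries would raise weak candidates as well, but candidates below the threshold were at 0.956 times the length expectation. Draws of weaker thresholded peaks matched on GC content had a mean of 20.97% on X, with the central 95% of draws ending at 29%, which argues against GC content. The word GCGCAGGG, part of the motif known from recruitment sites of the dosage compensation complex on X, lay within 150 bp of the summit in 39.5% of those X peaks and in 1.61% of the autosomal peaks among the 100 strongest (Fisher's exact test, p = 7.3e-07). A candidate explanation for the peaks with the word is that tagged DUXL-1, or the precipitation itself, recovered sites occupied by that complex. Only 15 of the 38 X peaks had the word. The search took exact matches of this part of the motif, so it does not show that the other X peaks lie outside such sites. Most of the X peaks are left without an explanation. Occupancy by that complex was not measured and no control precipitation is analysed here. The explanation was therefore not tested, and others stay open.

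The second pattern is the peaks at tRNA genes. If reads shared between identical copies were the only source, tRNA genes whose sequence occurs once would rarely have a peak. Of 140 such genes, 31.4% had one (interval 24.3 to 39.5), which argues against that source alone for them. Copies were counted by exact match of the whole gene, so reads shared with nearly identical genes are not excluded. Nor is a peak that belongs to a neighbouring gene within 100 bp. Genes with several copies had a peak in 49.8% (Fisher's exact test, p = 0.000153), and for these a contribution of shared reads cannot be told apart from other differences between the genes. Random windows matched to the GC content of tRNA genes had a peak in 1.04%, against 45.6% of the genes, which argues against GC content. Strong transcription or open chromatin at these genes, independent of DUXL-1, was not tested. The same holds for the peaks at the gene lists and for the words at the summits.

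The third pattern is the density of candidates around duxl-1. Candidates were 2.68 times as dense within 20 kb as 20 to 60 kb away (38 against 27, exact binomial test, p = 0.000112), which met the first bound set for extra copies in the transgene. That ratio largely restates the density itself, so a comparison was added after it had been seen: of 536 random windows elsewhere with at least as many candidates, 47.4% reached it. Extra copies therefore cannot be told apart from other sources of a dense window. Binding at promoters as elsewhere would place these candidates at promoters, and 55.3% of them were, against 32.4% of all pooled candidates (Fisher's exact test, p = 0.00473). The share is thus higher than elsewhere, and how much of this stretch consists of promoters was not measured. It therefore does not separate binding at promoters from extra copies.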

How the results depend on the processing

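The main results were recomputed under the alternatives, but the correlation of replicate signals, the signal bands and the named peaks were not. Alternatives on small RNA and other non-coding genes, the 100 strongest peaks and their cluster, the ce10 peak number, X against autosomes, the central part of single chromosomes, words of 6 bases, distance to starts and GC content were chosen after seeing the data. Of 91 alternative values of the main results, 77 kept their direction and side of the threshold, or stayed within the limits set for values without a test. The share of peaks found in both replicates moved from 52.2% to 85.2% in the 990 peaks with the highest signal, 36.5% with a reciprocal overlap of 50% and 46.9% with summits within 100 bp. It was 53.9% to 54.1% with either replicate's own top list. Since each list overlaps itself, these values only restate the overlap of the replicates' top lists. They are counted among the 77 but are no separate check. The number of gene lists that passed moved from 6 to 2 (ribosomal proteins and heat shock) in the stronger 990 peaks, which leave fewer genes with a peak, and to 1 with circular shifts. With upstream length as a covariate, collagens and neuropeptides no longer passed. Their odds ratios were then 0.247 and 0.243, computed without the constant that the main odds ratios hold. The ratio for X was reversed, at 0.948, without peaks at small RNA genes. The X ratio of the 100 strongest peaks stayed between 1.64 (200 strongest) and 2.83 (50 strongest) under these alternatives and was 1.8 without its densest 200 kb. In the 25 strongest nuclear peaks, which were not among the alternatives, it was 3.85. The promoter share ranged from 41.9% to 75.3% with other windows and gene sets and passed each time. The odds ratio of tRNA genes on X against autosomes, 1.35, newly passed at 1.4996 in the stronger 990 peaks and without replicate 1 (1.38 to 1.42 without either). The median distance to a start moved from 544 bp to 482 bp in the stronger 990 peaks and 608 to 670 bp with either replicate's own list, and GC content from 46.5% to 48.0% and 45.5%. Of 366 alternative values for single chromosomes, features, gene classes, lists and words, 304 kept their direction and side of the threshold, 35 no longer passed, 7 newly passed and 20 reversed, 17 of which passed in neither setting. The reversed ones were chromosome I (0.977 to 1.00) and the 3 prime UTR (0.811 to 1.05), both only without replicate 1, the 5 prime UTR (0.858 to 1.35), only without replicate 2, chromosome II at 0.979 with pooled candidates as background, intergenic sequence at 1.11 with lower-ranked candidates as background, and TGATAA, TAATNNATTA and TAATYNAATTA at 1.54, 2.73 and 2 with shuffled windows. The central share reversed on chromosome II (32.4%) and IV (33.1%) in the stronger 990 peaks and on IV without replicate 2 only (32.4% to 37.7%). Among gene lists, homeobox reversed without replicate 2 only (0.806 to 1.18), without peaks at small RNA genes (0.985) and with circular shifts (0.799). The main odds ratio of the homeobox list, 1.05, lay above 1 only through the constant added to each count. The observed share, 6.60% against 6.72% of other genes, was already slightly lower, so these are no true reversals. That constant also weighs on other lists with few peaks, and values with circular shifts are ratios of shares. Pharynx reversed in the stronger 990 peaks (0.958), from 500 bp upstream to 100 bp downstream (0.913) and with circular shifts (0.949). Germline reversed with circular shifts (0.992) and upstream length as covariate (0.964), and Wnt, Notch and EGF signalling in the stronger 990 peaks (1.13). Except where stated, the cause was not tested. The unknown read depth limits what can be said of weak peaks. No paired analysis was possible because the series has 1 group.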

Other observations

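The tests in this part were chosen after the data were seen. Several of the strongest peaks lay close together near the left end of X. Between X 1796255 and 1989776, within 200 kb, there were 9 of the 100 strongest nuclear peaks and 20 thresholded peaks in all, 2 of them at tRNA genes. Draws of 100 peaks from all nuclear thresholded peaks had at most 7 in any 200 kb, with a mean highest count of 3.08 (permutation p = 1e-04, the smallest that 10000 draws can give). In a further test, which kept the number drawn from each chromosome (38 on X), draws had at most 9, with a mean of 3.47 (permutation p = 0.0002). The strongest peak of the stretch was the one at meg-3.

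Words and gene classes differed between thresholded peaks and candidates below the threshold, and some changed little within the thresholded peaks. In the 100 strongest nuclear peaks, the next 400, the other thresholded peaks and the candidates below the threshold, GAGAGA was present in 22%, 22.2%, 20.8% and 8.93% of windows. ACGCAG was present in 18%, 17.2%, 13.3% and 3.47%, TAAT in 33%, 35.2%, 43.1% and 53.6%, and GC content was 49.8%, 49.0%, 45.6% and 40.2%. Peaks at tRNA genes made up 4% of the 100 strongest, 18.2% of the next 400, 12.9% of the other thresholded peaks and 0.542% of candidates below the threshold. For snoRNA genes these shares were 6%, 11.5%, 1.98% and 0.257%.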
